A study of Mus musculus with 48 samples.

How the data were processed

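The series holds mouse RNA of polyA type, made with a stranded kit, from cells sorted from digested nodes. Per the submitters' processing notes reads were aligned with STAR to GRCm38, quantified with RSEM 1.3.0 and tested with DESeq2 1.38.3. The expected counts analysed here were made by the authors with RSEM and deposited as whole numbers. The authors also deposited TPM of the dendritic cells, made with RSEM. The macrophage TPM were deposited by the authors with decimals dropped and are treated here as a score, since their sums fall short of the usual total. TPM and score served only to check columns, and each of 24 columns of a counts table matched its own column best. Columns of the dendritic cells named for tumor or wild type were read as TDLN or LN, the latter by elimination. Published comparisons of the submitters were not used here. Reads were not analysed here.

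Tables held 55487 genes, of which 99.4% had a symbol in GENCODE vM21 on GRCm38. Coordinates are from that annotation. Genes were kept with edgeR's filterByExpr by group and scaled with TMM. edgeR 4.0.16 quasi-likelihood tests were run on 1 model of 4 groups per cell type (12 libraries), and on 1 model of 8 groups (24 libraries) for MSM against SSM and for mDC against rDC. The p were adjusted by Benjamini-Hochberg with a limit of 0.05. Standard errors are the log2 fold change over the root of the F statistic. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

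The model, the 39 gene lists, the rule for naming genes and most of the other fits were fixed before the data were examined. Named genes pass 0.05, average at least 4 CPM over the compared libraries and, node differences aside, do not overlap between groups. The largest changes were named, 8 per direction for cisplatin in the TDLN, 5 for cisplatin in the LN and for TDLN against LN, 10 for the pair comparisons and 3 for node differences. Il33 and Il1rl1 were reported everywhere, with up to 4 members per list. Predicted, immunoglobulin, T cell receptor and Y genes and Xist were not named. Part of the genes so named, and of the called lists, is printed, and some of them are not reported here.

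Other fits chosen beforehand were DESeq2, its size factors, no low-count filter, the 6 compared libraries alone, a replicate block and leaving out each library. Added after the data were seen were fits without 4 macrophage libraries, without the MSM LN cisplatin group, without both, and with dendritic cell libraries above 5 M counts thinned to 3 M.

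In a self-test 200 genes were changed in simulated counts of the same size and spread. Of 4-fold changes 42 to 50% were recovered in macrophage comparisons of 3 against 3 and 95 to 100% in those of dendritic cells. Of 2-fold changes the shares were 6 to 15% and 68 to 85%, and 2 to 14 unchanged genes were called. Common coefficients of variation were 0.418 in MSM, 0.403 in SSM, 0.0625 in mDC and 0.105 in rDC.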

Results

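RNA was measured in 4 types of myeloid cell sorted from digested lymph nodes of mice. They were medullary sinus macrophages (MSM) and subcapsular sinus macrophages (SSM), which line the lymph sinuses and take up material carried in by lymph, migratory dendritic cells (mDC), which arrive from tissue, and resident dendritic cells (rDC). Each type came from nodes labelled LN and from tumor-draining nodes (TDLN), after PBS or cisplatin, a platinum compound that crosslinks DNA. With 3 libraries per group there were 48 libraries in 16 groups. The labels do not say which tissue the LN nodes drained, nor that the 3 libraries of a group came from separate animals, so the p-values may measure only technical spread. Libraries held 6.46 to 10.43 M counts in macrophages and 2.00 to 3.84 M in 18 dendritic cell libraries. The 3 mDC TDLN PBS and 3 rDC LN PBS libraries were deeper, with 10.73 to 15.48 M. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while camera tests gene lists. Values in brackets after a gene are its log2 fold change ± standard error (or log2 difference between nodes), and CPM are mean ± SD with n = 3 per group. List sums are scaled within the 12 libraries of a cell type, CPM given for both groups of a comparison within its model, while CPM of Il33 and Il1rl1 and those given for 1 group alone are scaled over the 24 libraries of a table, so values of 1 gene can differ slightly.

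The study's title names IL-33, a cytokine released from stressed cells that signals through ST2, the product of Il1rl1. Il33 (ENSMUSG00000024810, GRCm38 chromosome 19, 29925114 to 29960718, plus strand) lay between 0 and 19.4 CPM in single libraries. In SSM it averaged 11.3 ± 10.1 CPM in LN PBS, 3.40 ± 1.29 in LN cisplatin, 2.44 ± 0.651 in TDLN PBS and 5.35 ± 4.54 in TDLN cisplatin. In MSM the means were 5.58 ± 9.66, 0, 6.03 ± 0.388 and 3.03 ± 5.25 CPM in the same order. In LN PBS 2 of 3 SSM and 1 of 3 MSM libraries had counts. MSM against SSM over all libraries gave a log2 fold change of -2.10 ± 1.2 (adjusted p = 0.222), and no macrophage comparison called Il33. Without the 4 libraries resembling the other label the value was -6.46 (adjusted p = 1.06e-12), set by MSM groups at 0 counts. In TDLN PBS Il33 was higher in MSM. That exclusion called 8 of the 15 uncalled Il33 and Il1rl1 values in macrophages, and 6 changed sign or became 0. The IL-33 and type 2 immunity list was called in no macrophage or rDC comparison. In mDC of the LN 3 of 11 members rose and 1 fell with cisplatin (5 and 1 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.0549 with an estimated correlation). In mDC the list was also lower in the TDLN than in the LN with PBS (1 higher, 5 lower, camera adjusted p = 0.0435, 0.17 with an estimated correlation). Its cisplatin effect was lower in the TDLN (1 higher, 4 lower, camera adjusted p = 0.0401, 0.139 with an estimated correlation).

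In dendritic cells Il33 averaged 0.302 to 3.13 CPM. In rDC of the LN it rose from 0.302 ± 0.0745 to 2.16 ± 0.779 CPM with cisplatin (log2 fold change 2.80 ± 0.65, adjusted p = 0.00726, 24 against 13 counts), a call lost without replicate 2 of rDC LN CIS (adjusted p = 0.0555). Averaged over the conditions it was slightly higher in mDC than rDC (log2 fold change 0.75 ± 0.30, adjusted p = 0.0253). The call was lost without mDC TDLN CIS 3, mDC LN CIS 2, mDC LN PBS 2 or rDC TDLN PBS 1 (adjusted p = 0.0695, 0.0531, 0.0633 and 0.0561). With PBS mDC had the higher means (1.90 against 0.865 CPM in the TDLN and 2.29 against 0.302 in the LN). With cisplatin they had the lower (2.24 against 3.13 and 1.5 against 2.16). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415, plus strand) fell in MSM of the LN from 31.4 ± 17.9 to 1.01 ± 0.722 CPM with cisplatin (log2 fold change -4.93 ± 0.79, adjusted p = 0.000891). The macrophage gene Adgre1 was lower there too (3.65 against 424 CPM), so other cells in the sort may account for this and the node difference. In MSM of the TDLN it rose from 11.9 ± 0.466 to 48.0 ± 30.7 CPM (log2 fold change 2.03 ± 0.65, adjusted p = 0.0332), a call lost without replicate 1, 2 or 3 of MSM TDLN PBS (adjusted p = 0.104, 0.107 and 0.101) or replicate 2 or 3 of MSM TDLN CIS (adjusted p = 0.105 and 0.0832). Il1rl1 was lower in mDC than in rDC (log2 fold change -0.75 ± 0.26, adjusted p = 0.0101), and after the deep libraries were thinned the adjusted p was 0.0554. The node difference of the cisplatin effect in MSM was called for Il1rl1 (6.96 ± 1.0, adjusted p = 0.000445), and other comparisons testing these genes called neither with all libraries included.

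**Figure D1:**
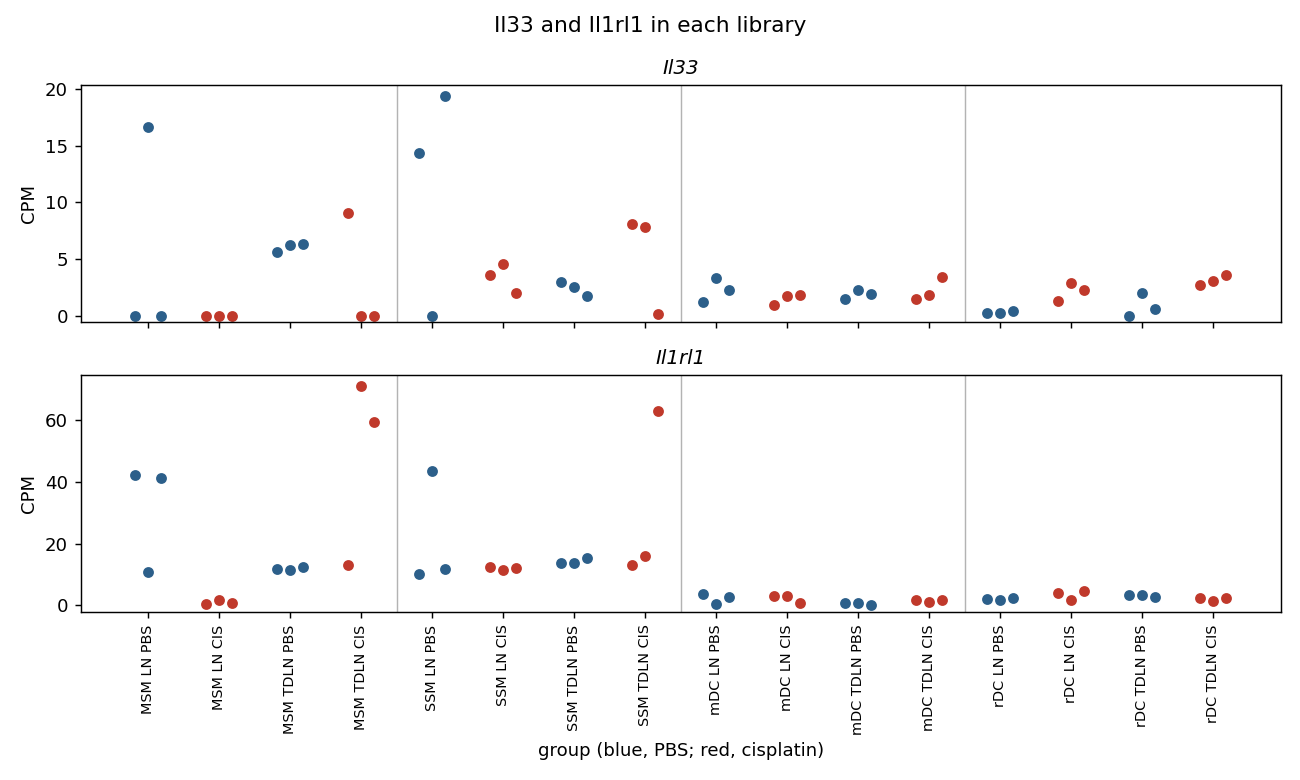
Il33 (upper panel) and Il1rl1 (lower panel) in CPM for each of the 48 libraries, by group on the x axis, blue for PBS and red for cisplatin, 1 point per library. Il33 lies between 0 and 19.4 CPM, and within MSM LN PBS 1 library stands at 16.7 CPM and the others at 0.

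The first comparison asked how MSM and SSM differ over all 4 conditions (12 libraries each). Averaged over the conditions, genes typical of sinus macrophages, interferon response genes and cell cycle genes were lower in the libraries labelled MSM, but not within each condition. Of 19671 genes tested, 1518 were higher and 4424 lower in MSM. Within LN PBS and TDLN cisplatin, 1 library of each label resembled the other label. These crossed libraries, MSM LN PBS 2, SSM LN PBS 2, MSM TDLN CIS 1 and SSM TDLN CIS 3, correlated across genes with a mean log2 CPM above 4 at 0.989 or more with the libraries of the other label and at 0.747 or less with their own. In list sums they can stand apart from the other libraries of their group. No gene separated all 12 MSM from all 12 SSM libraries. Without the 4 crossed libraries 11624 genes passed, and all 265 called values of named macrophage genes kept their calls.

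In the lymph node macrophage list, 0 of 12 were higher and 10 were lower (the same adjusted over the list alone, median log2 -0.92, camera adjusted p = 0.000837, adjusted p = 0.443 with an estimated correlation). In LN cisplatin the list summed to 1875.7 to 1964.8 CPM in MSM and 23004.6 to 23367.7 CPM in SSM. In TDLN PBS it was higher in MSM, at 22998.3 to 23314.5 against 12009.9 to 12403.5 CPM. Among its members were Csf1r (-0.90 ± 0.16, adjusted p = 0.000331), the receptor for the macrophage growth factor CSF1, and the Fc receptor gene Fcgr1 (-4.87 ± 0.74, adjusted p = 5.01e-05). For Lyz2 (-0.68 ± 0.063, adjusted p = 1.77e-07) and Maf (-0.36 ± 0.090, adjusted p = 0.00457) the direction turned in 1 fit (0.30 and 0.45). It left out the 4 libraries together with the LN cisplatin groups of MSM and SSM. Of medullary sinus macrophage markers, 0 of 10 were higher and 8 lower (0 and 10 adjusted over the list alone, median log2 -2.40, camera adjusted p = 0.00211, 0.69 with an estimated correlation). Slc40a1 (-1.05 ± 0.15, adjusted p = 2.18e-05) and Marco (-3.81 ± 1.2, adjusted p = 0.0206) were lower in MSM, contrary to the label. In MSM only crossed libraries exceeded 4.63 CPM of Marco. Adgre1 (-1.42 ± 0.24, adjusted p = 0.000179), the F4/80 gene, became 1.06 without them and MSM LN cisplatin. In the efferocytosis and scavenging list, 2 of 23 were higher and 16 were lower (2 and 18 adjusted over the list alone, median log2 -1.14, camera adjusted p = 0.000837). Among them were Msr1 (-1.68 ± 0.078, adjusted p = 5.42e-11) and Lrp1 (-2.80 ± 0.22, adjusted p = 1.91e-08).

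The type I interferon list was also lower in MSM: 0 of 32 were higher and 27 were lower (the same adjusted over the list alone, median log2 -0.87, camera adjusted p = 1.85e-12, adjusted p = 0.175 with an estimated correlation). In LN PBS the list sum was not lower in MSM, at 3773.9, 2740.8 and 3713.3 against 2681.3, 3701.8 and 2672.8 CPM. Examples were Slfn5 (-1.21 ± 0.10, adjusted p = 4.76e-08), Parp14 (-1.98 ± 0.17, adjusted p = 6.22e-08) and Usp18 (-0.59 ± 0.056, adjusted p = 2.13e-07). Among proliferation genes, 0 of 30 were higher and 18 were lower (0 and 20 adjusted over the list alone, median log2 -1.0, camera adjusted p = 1.45e-05, adjusted p = 0.69 with an estimated correlation). The list sum was lower in MSM in TDLN PBS (500.1 to 527.4 against 1103.1 to 1143.2 CPM) but higher in LN cisplatin (1113.7 to 1136.0 against 933.5 to 970.2 CPM). Named members were Top2a (-2.02 ± 0.13, adjusted p = 2.39e-09) and Mki67 (-1.29 ± 0.094, adjusted p = 8.14e-09). No gene met every condition for being named by size of change, and genes with the smallest p included Ampd3 (-2.99 ± 0.079, adjusted p = 3.16e-13) and Il13ra1 (-2.22 ± 0.095, adjusted p = 2.79e-11). Il13ra1 turned to 0.12 without the 4 libraries and the MSM LN cisplatin group. The camera test called 9 of 39 lists here and 1 with an estimated correlation.

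**Figure D2:**
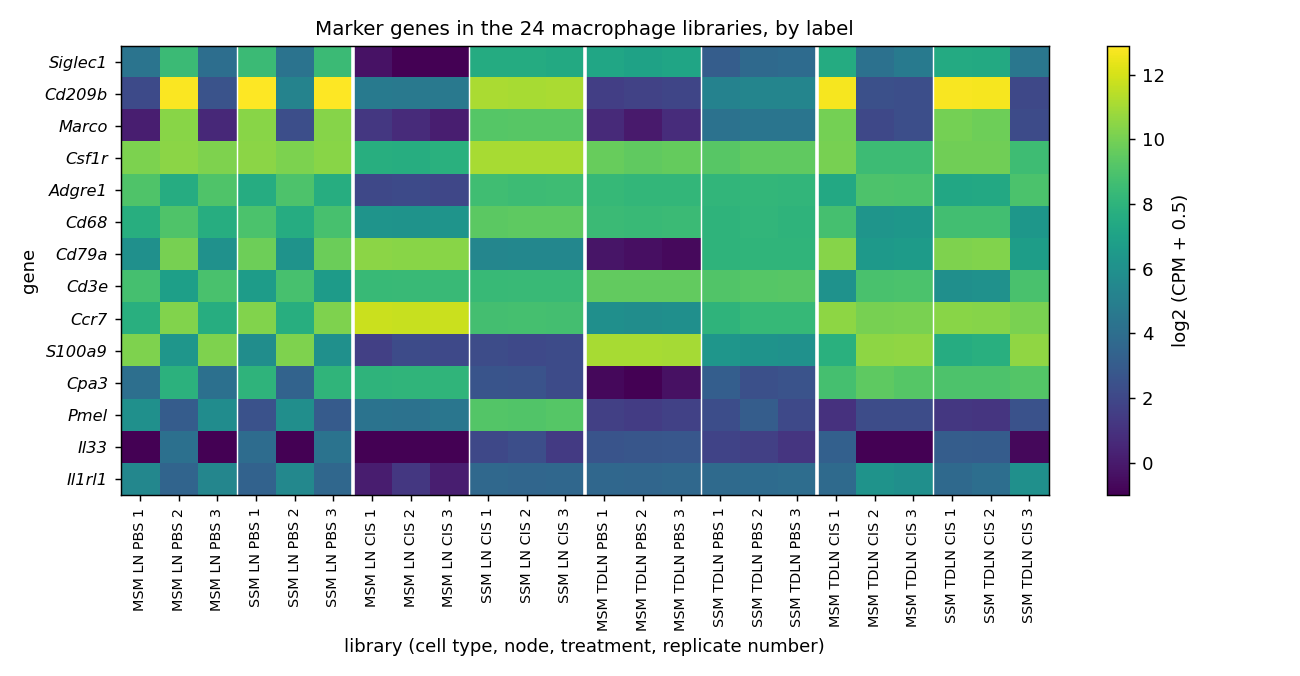
Marker genes (y axis) in each of the 24 macrophage libraries (x axis, by label), coloured by log2 (CPM + 0.5). The columns MSM LN PBS 2, SSM LN PBS 2, MSM TDLN CIS 1 and SSM TDLN CIS 3 carry the pattern of most libraries of the other label in their condition. Siglec1 averages 0.0957 CPM in MSM LN CIS.

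What cisplatin changed in MSM of tumor-draining nodes was tested with 3 against 3 libraries. Cell cycle genes, mast cell genes and B cell genes rose, and several lysosomal genes fell. Of 17002 genes 4357 rose and 1948 fell. Without the crossed libraries 12674 passed. In the tested genes 52.6% did not overlap between the groups, against 10% by chance.

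Of the proliferation list, 22 of 30 rose and 0 fell (the same adjusted over the list alone, median log2 3.45 with 0 counts at the bound, camera adjusted p = 1.78e-05, adjusted p = 0.634 with an estimated correlation). Its sum was 1222.5 CPM in the crossed CIS 1, 659.3 and 635.4 in CIS 2 and 3 and 500.1 to 527.4 in PBS. The DNA topoisomerase gene Top2a stood at 35.0 ± 7.63 against 0.255 ± 0.128 CPM and the proliferation marker Mki67 at 26.4 ± 1.48 against 0.681 ± 0.281 CPM.

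Markers of other cells moved with these groups. In the mast cell and basophil list, 9 of 10 rose and 0 fell (10 and 0 adjusted over the list alone, median log2 7.61 with 0 counts at the bound, camera adjusted p = 2.89e-05, adjusted p = 0.382 with an estimated correlation). The proteases Tpsb2 (at least 2150-fold higher, adjusted p = 0.00898), Cma1 (at least 1650-fold higher, adjusted p = 0.0106) and Mcpt4 (at least 1410-fold higher, adjusted p = 0.00884) and the IgE receptor gene Fcer1a (at least 119-fold higher, adjusted p = 5.34e-06) were at 0 counts in PBS. "At least" sets the group at 0 to 3 counts per library and covers counting error only. Tpsb2 has a close paralog, so its level is uncertain. Of the B cell list, 12 of 16 rose and 1 fell (13 and 1 adjusted over the list alone, median log2 4.72 with 0 counts at the bound, camera adjusted p = 0.0499, adjusted p = 0.78 with an estimated correlation). 1 of them was Cd79a (10.89 ± 1.9, adjusted p = 0.00174). The crossed library MSM TDLN CIS 1 carried much of this, with a B cell list sum of 13273.3 CPM against 2054.9 and 2033.3 in the other cisplatin libraries and 992.5 to 1035.9 in PBS. The chemokine receptor gene of follicular lymphocytes Cxcr5 (at least 421-fold higher, adjusted p = 0.00352) rose too.

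Other genes with the largest rises were Cx3cl1 (at least 322-fold higher, adjusted p = 0.000408), Slc45a3 (at least 314-fold higher, adjusted p = 0.00174), Snn (at least 259-fold higher, adjusted p = 0.0126) and Slc15a4 (at least 239-fold higher, adjusted p = 2.24e-05). The largest falls were in Slc6a8 (at least 39.3-fold lower, adjusted p = 0.00105), Lrp11 (at least 38.1-fold lower, adjusted p = 0.000193), Enho (at least 27.4-fold lower, adjusted p = 0.00484), Ank1 (at least 23.3-fold lower, adjusted p = 0.00041), Fgfr3 (0.0338 against 13.8 CPM, adjusted p = 0.00113) and Lin28a (0.0338 against 11.2 CPM, adjusted p = 0.00058) and AC166110.3 (at least 43.0-fold lower, adjusted p = 0.000692). Of the lysosome list, 0 of 26 rose and 8 fell (0 and 4 adjusted over the list alone, median log2 -0.49, camera adjusted p = 0.000964, adjusted p = 0.413 with an estimated correlation), led by the protease gene Ctsd (-1.40 ± 0.14, adjusted p = 6.26e-05), and by Mcoln1 (-0.52 ± 0.12, adjusted p = 0.00623) and Gusb (-0.65 ± 0.16, adjusted p = 0.00974). Of 39 lists 9 were called, 0 with an estimated correlation.

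In MSM of the LN cisplatin was compared with PBS (3 against 3). Macrophage, scavenging and neutrophil genes fell. Of 17002 genes 2819 rose and 4557 fell. Without the crossed libraries 13602 passed. In MSM LN cisplatin Siglec1, a sinus macrophage lectin, was at 0.0957 ± 0.166 CPM and Adgre1 at 3.65 ± 0.257, while the chemokine receptor gene Ccr7 was at 3500 ± 96.4, the B cell gene Cd79a at 1390 ± 36.1 and the dendritic cell gene Zbtb46 at 96.9 ± 6.13 CPM.

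In the lymph node macrophage list, 0 of 12 rose and 11 fell (the same adjusted over the list alone, median log2 -2.65, camera adjusted p = 0.000341, adjusted p = 0.493 with an estimated correlation). Lysozyme gene Lyz2 stood at 1507 ± 36.3 against 10960 ± 982 CPM, and Lyz2 (-2.86 ± 0.15, adjusted p = 1.28e-06), Csf1r (-2.55 ± 0.35, adjusted p = 0.000366), Maf (-2.66 ± 0.21, adjusted p = 1.37e-05) and Cd14 (-2.45 ± 0.31, adjusted p = 0.000219) all fell. Of efferocytosis and scavenging genes, 2 of 23 rose and 18 fell (2 and 19 adjusted over the list alone, median log2 -3.18, camera adjusted p = 0.000341, adjusted p = 0.107 with an estimated correlation). Their sum was 5172.8 CPM in the crossed PBS 2, 1571.9 and 1564.3 in PBS 1 and 3 and 681.9 to 742.6 after cisplatin. Among them were Colec12 (-3.76 ± 0.26, adjusted p = 6.17e-06) and Lrp1 (-8.08 ± 0.64, adjusted p = 1.32e-05). 

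Of neutrophil genes, 0 of 15 rose and 14 fell (the same adjusted over the list alone, median log2 -7.26 with 0 counts at the bound, camera adjusted p = 0.00016, adjusted p = 0.778 with an estimated correlation). The list summed to 307.0 to 325.5 CPM after cisplatin, against 8419.4 and 8165.6 in PBS 1 and 3 and 645.5 in the crossed PBS 2. The granule protein genes Ltf (at least 2540-fold lower, adjusted p = 0.00329) and Camp (at least 666-fold lower, adjusted p = 0.00722) and the surface protein gene Cd177 (at least 435-fold lower, adjusted p = 0.00104) were at 0 counts, as were G0s2 (at least 360-fold lower, adjusted p = 0.000219) and Inpp5j (at least 359-fold lower, adjusted p = 0.00253). Another neutrophil gene was S100a9 (-7.89 ± 1.1, adjusted p = 0.000461). Of the NK and innate lymphoid list, 6 of 13 rose and 0 fell (the same adjusted over the list alone, median log2 1.54, camera adjusted p = 0.000341, adjusted p = 0.54 with an estimated correlation). The crossed PBS 2 carried much of this, with a sum of 209.9 CPM against 1049.9 and 1070.8 in PBS 1 and 3 and 1235.6 to 1337.6 after cisplatin. Among them were Gzma (58.6 against 0.0725 CPM, adjusted p = 2.89e-05) and Prf1 (2.71 ± 0.28, adjusted p = 6.32e-05). The Notch ligand gene Dll4 (at least 73.0-fold higher, adjusted p = 0.00265) and Kif26b (at least 34.2-fold higher, adjusted p = 0.0013), Zfp583 (at least 32.1-fold higher, adjusted p = 1.72e-05) and Pcdhb17 (at least 29.9-fold higher, adjusted p = 0.000718) rose from 0 counts. Of 39 lists 10 were called, 0 with an estimated correlation.

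MSM of the TDLN and the LN were compared with PBS (3 against 3), which mixes node site with tumor drainage. Interferon, cell cycle and mast cell genes were lower in the TDLN. Of 17002 genes 1974 were higher and 4515 lower, and 12812 passed without the crossed libraries. In the type I interferon list, 0 of 32 were higher and 17 were lower (the same adjusted over the list alone, median log2 -1.15 with 0 counts at the bound, camera adjusted p = 0.00129, adjusted p = 0.704 with an estimated correlation). Among them were Parp14 (-8.13 ± 0.57, adjusted p = 7.02e-06) and Zbp1 (-1.77 ± 0.17, adjusted p = 4.67e-05). Of proliferation genes, 0 of 30 were higher and 23 were lower (the same adjusted over the list alone, median log2 -3.02 with 0 counts at the bound, camera adjusted p = 1.48e-05, adjusted p = 0.704 with an estimated correlation). Among them were Top2a (-6.40 ± 0.35, adjusted p = 2.21e-06) and Mki67 (-3.95 ± 0.30, adjusted p = 1.05e-05).

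Of mast cell and basophil genes, 0 of 10 were higher and 7 were lower (0 and 9 adjusted over the list alone, median log2 -7.08 with 0 counts at the bound, camera adjusted p = 0.00553, adjusted p = 0.535 with an estimated correlation). Most of the LN signal lay in the crossed PBS 2, at 1119.5 CPM against 156.8 and 156.6 in PBS 1 and 3 and 50.4 to 60.2 in the TDLN. Among them were Fcer1a (at least 47.5-fold lower, adjusted p = 1.03e-05) and the transcription factor gene Gata2 (at least 95.4-fold lower, adjusted p = 4.09e-05). Tpsb2, Cma1 and Mcpt4 (adjusted p = 0.0216, 0.0251 and 0.0216) lost their calls without replicate 1, 2 or 3 of MSM TDLN PBS, with adjusted p from 0.0579 to 0.0675. The follicular receptor gene Cxcr5 (at least 334-fold lower, adjusted p = 0.00388) and the peptide transporter gene Slc15a4 (at least 266-fold lower, adjusted p = 2.08e-05) were lower as well. The immediate early gene Egr4 (at least 96.3-fold higher, adjusted p = 0.00617), the endothelial transcription factor gene Erg (at least 25.8-fold higher, adjusted p = 0.00149), Nrbp2 (at least 23.3-fold higher, adjusted p = 0.000579) and Ccdc157 (17.0 against 0.0362 CPM, adjusted p = 0.000469) were higher. Of 39 lists 5 were called, 0 with an estimated correlation.

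In SSM of the TDLN cisplatin was set against PBS with 3 against 3 libraries. Interferon response genes fell while mast cell genes rose. Of 16886 genes 2203 rose and 1680 fell. Leaving out any 1 of the 6 libraries moved the total of 3883 by more than 1.5 times, to 8810 without SSM TDLN CIS 3, 2237 and 2248 without CIS 1 and 2, and 1988, 1818 and 1864 without PBS 1, 2 and 3. Without the crossed libraries it was 12540.

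In the type I interferon list, 0 of 32 rose and 27 fell (0 and 31 adjusted over the list alone, median log2 -1.69, camera adjusted p = 2.62e-21, adjusted p = 0.0987 with an estimated correlation). The ISG15 protease gene Usp18 stood at 35.3 ± 6.40 against 212 ± 11.9 CPM. Usp18, Ifit2 (-3.80 ± 0.37, adjusted p = 0.000303), Zbp1 (-1.93 ± 0.22, adjusted p = 0.000544) and Parp14 (-1.49 ± 0.18, adjusted p = 0.000607) fell, the first with a log2 fold change of -2.59 ± 0.14 (adjusted p = 2.49e-05). Members of the resident cDC1 list, which marks cross-presenting dendritic cells, followed: 1 of 11 rose and 6 fell (2 and 6 adjusted over the list alone, median log2 -1.36, camera adjusted p = 0.00867, adjusted p = 0.115 with an estimated correlation). Among them were the chemokine receptor gene Xcr1 (-3.32 ± 0.46, adjusted p = 0.00136) and Cadm1 (-1.61 ± 0.20, adjusted p = 0.000792).

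Of T cell genes, 0 of 18 rose and 4 fell (the same adjusted over the list alone, median log2 -1.42, camera adjusted p = 9.11e-05, adjusted p = 0.795 with an estimated correlation). The list summed to 733.7 and 759.2 CPM in CIS 1 and 2, while the crossed CIS 3 (5075.9) stayed near PBS (5262.2 to 5415.4). Among them were Foxp3 (-2.14 ± 0.42, adjusted p = 0.00648), the regulatory T cell factor gene. In the mast cell list, 8 of 9 rose and 0 fell (the same adjusted over the list alone, median log2 6.43 with 0 counts at the bound, camera adjusted p = 1.55e-07, adjusted p = 0.115 with an estimated correlation). Among them were Fcer1a (7.42 ± 0.45, adjusted p = 2.55e-05), Cpa3 (6.43 ± 0.97, adjusted p = 0.00215), Gata2 (3.58 ± 0.44, adjusted p = 0.00076), Cma1 (at least 1520-fold higher, adjusted p = 0.0049), Mcpt4 (438 against 0.0816 CPM, adjusted p = 0.00573) and Tpsb2 (11.90 ± 2.0, adjusted p = 0.00558), the last uncertain because of its paralog.

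Other large rises were Slc45a3 (at least 264-fold higher, adjusted p = 0.00157), Mrgprb1 (at least 149-fold higher, adjusted p = 0.0124) and the Notch ligand gene Dll1 (at least 109-fold higher, adjusted p = 0.00316). Rises of Bpifb2 (at least 869-fold higher, adjusted p = 0.0197) and Ltf (734 against 0.0816 CPM, adjusted p = 0.0309) were lost without replicate 1, 2 or 3 of SSM TDLN PBS, at adjusted p = 0.0585, 0.0614 and 0.0593 for Bpifb2 and 0.105, 0.11 and 0.118 for Ltf. Large falls were Peg3 (at least 34.5-fold lower, adjusted p = 0.00625), Pdzk1ip1 (at least 25.1-fold lower, adjusted p = 0.000496), Spint1 (0.110 against 11.6 CPM, adjusted p = 0.00772), Pde10a (-6.20 ± 0.57, adjusted p = 0.000233), Hhat (-5.73 ± 0.85, adjusted p = 0.00199), the scavenging chemokine receptor gene Ackr3 (-5.43 ± 0.88, adjusted p = 0.00294) and Igdcc4 (-5.30 ± 0.91, adjusted p = 0.00368). Of 39 lists 6 were called, 0 with an estimated correlation.

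In SSM of the LN (3 against 3) interferon response, melanocyte and glycolysis genes were higher with cisplatin, and B cell and mast cell genes were lower. Of 16886 genes 987 rose and 1253 fell. The total of 2240 became 4441 without SSM LN PBS 2, 1181 and 1105 without PBS 1 and 3, and 803, 823 and 831 without CIS 1, 2 and 3. Without the crossed libraries it was 10574, and with DESeq2 3554.

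Of type I interferon genes, 12 of 32 rose and 0 fell (21 and 0 adjusted over the list alone, median log2 0.77, camera adjusted p = 5.67e-10, adjusted p = 0.143 with an estimated correlation). Among them were Oas2 (1.53 ± 0.17, adjusted p = 0.000978) and Usp18 (1.13 ± 0.14, adjusted p = 0.00123). In the melanocyte and melanoma list, 5 of 10 rose and 0 fell (9 and 0 adjusted over the list alone, median log2 3.87 with 0 counts at the bound, camera adjusted p = 2.03e-11, adjusted p = 0.143 with an estimated correlation). The melanosome gene Pmel stood at 566 ± 23.6 against 23.9 ± 30.5 CPM, and Pmel (4.58 ± 0.88, adjusted p = 0.00963), Tyrp1 (4.82 ± 0.97, adjusted p = 0.0109) and tyrosinase Tyr (5.49 ± 0.59, adjusted p = 0.000781) rose. In the glycolysis and hypoxia list, 6 of 27 rose and 0 fell (10 and 0 adjusted over the list alone, median log2 0.57, camera adjusted p = 1.98e-05, adjusted p = 0.143 with an estimated correlation). Among them were Pgk1 (1.04 ± 0.11, adjusted p = 0.000781) and Eno1 (0.85 ± 0.12, adjusted p = 0.00217).

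In the B cell list, 0 of 16 rose and 9 fell (0 and 14 adjusted over the list alone, median log2 -3.71, camera adjusted p = 1.98e-05, adjusted p = 0.45 with an estimated correlation). The crossed PBS 2 ran the other way, with a sum of 1010.4 CPM against 1504.5 to 1519.8 after cisplatin and 10020.3 and 9904.6 in PBS 1 and 3. Its member Cd79a (-3.88 ± 0.97, adjusted p = 0.0261) lost the call without replicate 1 or 3 of SSM LN PBS (adjusted p = 0.0712 and 0.0718) or replicate 1, 2 or 3 of SSM LN CIS (adjusted p = 0.102, 0.102 and 0.103). Of the mast cell list, 0 of 9 rose and 7 fell (0 and 8 adjusted over the list alone, median log2 -3.35 with 0 counts at the bound, camera adjusted p = 1.98e-05, adjusted p = 0.143 with an estimated correlation). Among them were Cpa3 (-5.20 ± 0.93, adjusted p = 0.00688) and Gata2 (-2.24 ± 0.41, adjusted p = 0.00795). Falls of Tpsab1 (at least 123-fold lower, adjusted p = 0.0176), Mrgprb1 (at least 51.5-fold lower, adjusted p = 0.0296) and mt-Nd3 (at least 42.4-fold lower, adjusted p = 0.0354) were lost on leaving out single libraries. Tpsab1 gave adjusted p = 0.0599, 0.0595 and 0.0592 without CIS replicates 1, 2 and 3. Mrgprb1 lost it without replicate 1 or 3 of SSM LN PBS (adjusted p = 0.0724 and 0.0743) or replicate 1, 2 or 3 of SSM LN CIS (adjusted p = 0.0822, 0.0838 and 0.084), and mt-Nd3 without replicate 1 or 3 of SSM LN PBS (adjusted p = 0.0788 and 0.0833) or replicate 1, 2 or 3 of SSM LN CIS (adjusted p = 0.0961, 0.0978 and 0.0978). Among the largest rises were Sox10 (at least 36.5-fold higher, adjusted p = 0.00475), a melanocyte and glial transcription factor gene, Tbx2 (at least 34.8-fold higher, adjusted p = 0.00515), Lrrc29 (at least 26.1-fold higher, adjusted p = 0.00227) and Mboat2 (8.04 against 0.0318 CPM, adjusted p = 0.00667). The olfactory receptor gene Olfr523 (at least 27.2-fold higher, adjusted p = 0.0287) lost its call without replicate 1 or 3 of PBS or any CIS replicate (highest adjusted p = 0.0757). Of 39 lists 12 were called, 0 with an estimated correlation.

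TDLN against LN in SSM with PBS (3 against 3) showed higher interferon genes and lower macrophage and mast cell genes in the TDLN. Of 16886 genes 1289 were higher and 2032 lower. The total of 3321 became 1977, 6471 and 1900 without SSM LN PBS 1, 2 and 3, and 1672, 1400 and 1413 without SSM TDLN PBS 1, 2 and 3. It was 11947 without the crossed libraries. In the type I interferon list, 11 of 32 were higher and 1 was lower (14 and 1 adjusted over the list alone, median log2 0.74, camera adjusted p = 2.57e-06, adjusted p = 0.395 with an estimated correlation). Among them were Usp18 (2.11 ± 0.14, adjusted p = 5.05e-05) and Ifit2 (2.78 ± 0.36, adjusted p = 0.00107). Of lymph node macrophage genes, 0 of 12 were higher and 5 were lower (0 and 7 adjusted over the list alone, median log2 -1.39, camera adjusted p = 0.0122, adjusted p = 0.751 with an estimated correlation). Among them were Cd14 (-2.90 ± 0.37, adjusted p = 0.00101) and the RANK gene Tnfrsf11a (-1.99 ± 0.38, adjusted p = 0.00652). The lectin gene Siglec1 (-4.38 ± 1.0, adjusted p = 0.0146) lost its call without replicate 1, 2 or 3 of SSM TDLN PBS (adjusted p = 0.0661, 0.0633 and 0.0588).

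Of mast cell genes, 0 of 9 were higher and 6 were lower (the same adjusted over the list alone, median log2 -4.86 with 0 counts at the bound, camera adjusted p = 5.81e-05, adjusted p = 0.37 with an estimated correlation). Among them were Fcer1a (-6.31 ± 0.44, adjusted p = 5.05e-05) and Gata2 (-3.26 ± 0.44, adjusted p = 0.00128). Also lower was Slc45a3 (at least 104-fold lower, adjusted p = 0.00273). Higher were Ccdc157 (at least 44.7-fold higher, adjusted p = 0.00214), Ackr3 (8.42 against 0.0451 CPM, adjusted p = 0.00167) and Pdzk1ip1 (8.10 against 0.0318 CPM, adjusted p = 0.000715). Of the genes named for size, Bpifb2 (at least 696-fold lower, adjusted p = 0.0233), Bpifb3 (at least 568-fold lower, adjusted p = 0.0396), Olfr523 (at least 27.7-fold higher, adjusted p = 0.0215), Gbp2b (0.0408 against 162 CPM, adjusted p = 0.0177) and Peg3 (11.2 against 0.135 CPM, adjusted p = 0.0109) lost their calls in some runs with 1 library left out, at adjusted p up to 0.0738, 0.108, 0.0592, 0.0877 and 0.0509, each of these without an SSM PBS library of the LN or TDLN. Of 39 lists 9 were called, 0 with an estimated correlation.

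Whether cisplatin acted differently in the TDLN and the LN was tested as the difference of its log2 effects. In MSM 5289 genes had a higher and 1639 a lower effect in the TDLN (11954 in all without the crossed libraries). The median over all genes was 0.580, and 0.452 with DESeq2 size factors, so gene differences stand relative to that shift. Of the lymph node macrophage list, 10 of 12 were higher and 0 were lower (the same adjusted over the list alone, median log2 2.49, camera adjusted p = 0.0395, adjusted p = 0.732 with an estimated correlation). Among them were Maf (2.20 ± 0.28, adjusted p = 0.000208) and Lyz2 (1.45 ± 0.20, adjusted p = 0.000302). In the proliferation, neutrophil and mast cell lists 19 of 30, 14 of 15 and 9 of 10 members had a higher effect in the TDLN (19, 14 and 9 adjusted over the list alone). Their camera adjusted p was 0.0099, 0.0185 and 0.0132, and adjusted p = 0.751, 0.751 and 0.732 with an estimated correlation. With a replicate block the neutrophil and lymph node macrophage lists lost the call (adjusted p = 0.0818 and 0.0696).

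In SSM the interferon genes went opposite ways in both nodes. The effect was higher in the TDLN for 2262 genes and lower for 1387. The total of 3649 became 7440 without SSM TDLN CIS 3, 6317 without SSM LN PBS 2, 2170 and 2287 without SSM TDLN PBS 2 and 3, and 2212, 2174 and 2208 without SSM LN CIS 1, 2 and 3. It was 11607 without the crossed libraries. Of type I interferon genes, 0 of 32 were higher and 28 were lower (0 and 30 adjusted over the list alone, median log2 -2.95, camera adjusted p = 3.81e-28, adjusted p = 0.0615 with an estimated correlation). Among them were Usp18 (-3.72 ± 0.20, adjusted p = 1.08e-05) and Oas2 (-2.79 ± 0.25, adjusted p = 0.000188). In the B cell list, 15 of 16 were higher and 0 were lower (the same adjusted over the list alone, median log2 5.23, camera adjusted p = 7.87e-05, adjusted p = 0.567 with an estimated correlation). The crossed libraries opposed this, with sums of 2073.9 CPM in TDLN CIS 3 (12488.1 and 12306.8 in CIS 1 and 2) and 1010.4 in LN PBS 2. Among them were Bank1 (4.11 ± 0.86, adjusted p = 0.00905) and Fcrla (6.75 ± 1.4, adjusted p = 0.00994). In the mast cell list 8 of 9 members had a higher effect in the TDLN and 0 a lower (8 and 0 adjusted over the list alone, camera adjusted p = 1.16e-09, adjusted p = 0.111 with an estimated correlation). Among them were Fcer1a (8.67 ± 0.54, adjusted p = 2.61e-05) and Gata2 (5.82 ± 0.60, adjusted p = 0.000382).

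Migratory and resident dendritic cells were compared over all 4 conditions (12 libraries each). Every tested gene of the maturation and migratory lists was higher in mDC, and the genes of plasmacytoid cells, B cells and cDC1 were higher in rDC. Of 14548 genes 5177 were higher and 5652 lower in mDC. Of these, 4494 did not overlap between 12 and 12 libraries, against 7.4e-05% by chance.

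In the dendritic cell maturation list, 28 of 28 were higher and 0 were lower (the same adjusted over the list alone, median log2 4.07, camera adjusted p = 1.16e-95). Of the migratory list, 16 of 16 were higher and 0 were lower (the same adjusted over the list alone, median log2 6.10, camera adjusted p = 1.07e-78). The actin bundling gene Fscn1 stood at 9051 ± 810 against 71.4 ± 35.8 CPM, and the chemokine gene Ccl22 at 3266 ± 519 against 13.8 ± 7.78 CPM. Tests gave Fscn1 (7.18 ± 0.059, adjusted p = 6.05e-36), Ccl22 (8.10 ± 0.050, adjusted p = 1.09e-38), Ccr7 (3.72 ± 0.032, adjusted p = 1.20e-35) and Cacnb3 (8.27 ± 0.071, adjusted p = 1.20e-35). Also named by size were Insm1 (8.48 ± 0.11, adjusted p = 3.10e-31), Nudt17 (7.94 ± 0.083, adjusted p = 9.83e-34), Lad1 (7.78 ± 0.072, adjusted p = 7.59e-35), Eno2 (7.39 ± 0.077, adjusted p = 1.01e-33) and the cytokine signalling inhibitor gene Socs2 (7.23 ± 0.077, adjusted p = 1.65e-33). In the NF-kB list, 20 of 28 were higher and 7 were lower (the same adjusted over the list alone, median log2 2.10, camera adjusted p = 9.72e-14). Among them were Icam1 (3.23 ± 0.037, adjusted p = 6.37e-33) and Relb (3.83 ± 0.047, adjusted p = 3.86e-32).

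The MHC class I list was higher in mDC: 14 of 17 were higher and 3 were lower (the same adjusted over the list alone, median log2 1.20, camera adjusted p = 1.09e-06). Among them were B2m (1.67 ± 0.037, adjusted p = 5.81e-26) and Nlrc5 (1.98 ± 0.038, adjusted p = 1.16e-27). The MHC class II list was lower: 3 of 14 were higher and 11 were lower (the same adjusted over the list alone, median log2 -1.69, camera adjusted p = 4.06e-07). Among them were the peptide exchange genes H2-DMa (-2.42 ± 0.048, adjusted p = 3.73e-27), H2-DMb1 (-2.65 ± 0.043, adjusted p = 2.90e-29) and H2-Ob (-3.15 ± 0.048, adjusted p = 7.04e-30).

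Of plasmacytoid genes, 0 of 10 were higher and 10 were lower (the same adjusted over the list alone, median log2 -5.16, camera adjusted p = 2.82e-26). Among them were the lectin gene Siglech (-7.28 ± 0.057, adjusted p = 3.02e-36), Ccr9 (-5.40 ± 0.051, adjusted p = 9.47e-35), Tcf4 (-2.45 ± 0.036, adjusted p = 2.96e-30), Cd300c (-8.45 ± 0.17, adjusted p = 1.33e-25) and Cox6a2 (-7.73 ± 0.24, adjusted p = 4.40e-22). In the B cell list, 0 of 16 were higher and 16 were lower (the same adjusted over the list alone, median log2 -3.09, camera adjusted p = 1.64e-27). Its members include Fcmr (-3.17 ± 0.046, adjusted p = 1.79e-30). Of resident cDC1 genes, 1 of 11 was higher and 10 were lower (the same adjusted over the list alone, median log2 -2.68, camera adjusted p = 5.60e-09). Among them were Wdfy4 (-3.60 ± 0.054, adjusted p = 4.50e-30) and Naaa (-3.73 ± 0.060, adjusted p = 1.88e-29). Further genes lower in mDC were Exosc6 (-8.06 ± 0.38, adjusted p = 3.98e-15), Eldr (-6.48 ± 0.17, adjusted p = 6.43e-24), Gzmc (-6.23 ± 0.23, adjusted p = 3.45e-19), Smim5 (-6.13 ± 0.10, adjusted p = 7.19e-29), Klk1b27 (-5.79 ± 0.30, adjusted p = 9.63e-17) and the terminal transferase gene Dntt (-5.85 ± 0.14, adjusted p = 1.68e-25). In the IL-33 and type 2 immunity list 7 of 17 members were higher and 7 lower (7 and 7 adjusted over the list alone). Its median was -0.06, its mean 0.70 and the camera test pointed up (adjusted p = 0.0343, adjusted p = 0.0482 with an estimated correlation). Of 36 lists 16 were called, 15 with an estimated correlation.

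**Figure D3:**
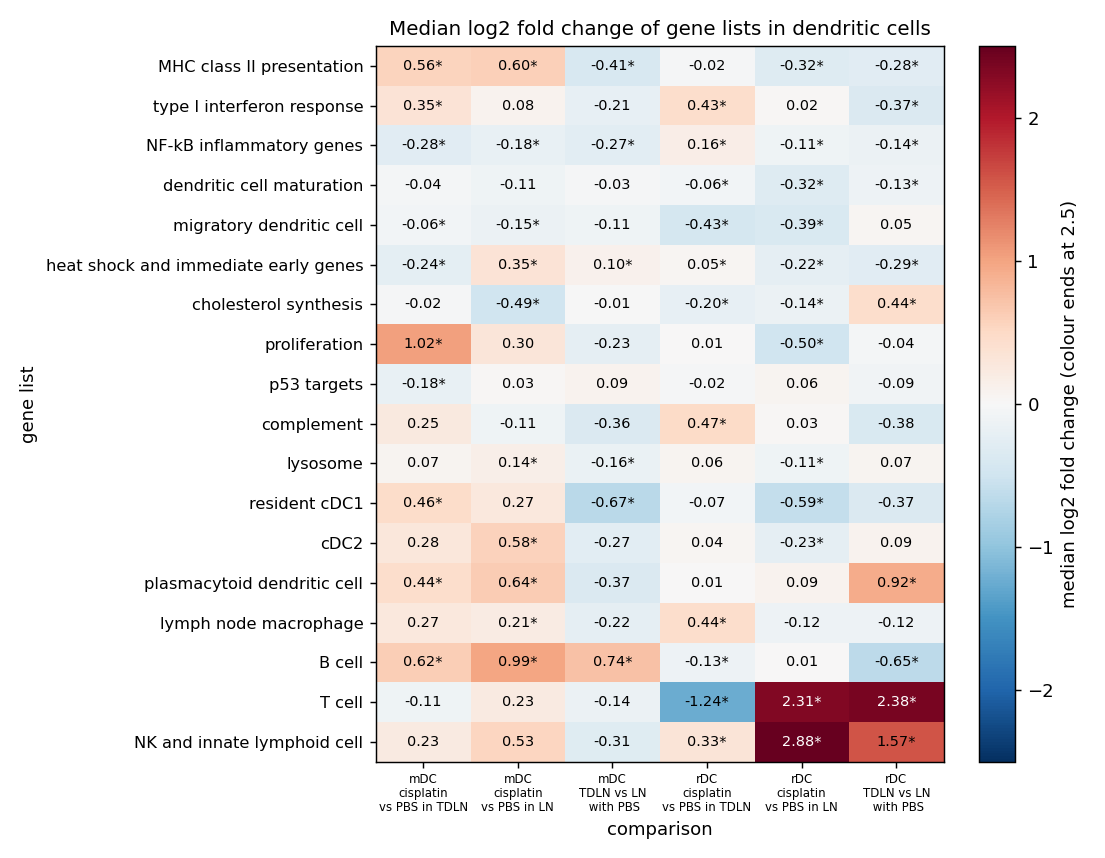
Median log2 fold change of 18 gene lists (y axis) in 6 comparisons of dendritic cells (x axis), with the value printed and the colour scale ending at 2.5, and a star marks a camera adjusted p below 0.05. T cell genes stand at -1.24, 2.31 and 2.38 in the rDC columns and at -0.11, 0.23 and -0.14 in the mDC columns.

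For mDC of the TDLN, cisplatin against PBS (3 against 3) raised genes of antigen presentation on MHC class II, cell division and B cells. Genes of NF-kB inflammation and immediate early response fell. Of 12519 genes 1768 rose and 1648 fell, and 43.7% did not overlap (10% by chance). With no low-count filter 9422 passed, and 2504 with the deep PBS libraries thinned. What went with their depth cannot be told apart from this group in any test.

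Of MHC class II genes, 10 of 14 rose and 0 fell (11 and 1 adjusted over the list alone, median log2 0.56, camera adjusted p = 7.38e-16). H2-Ab1 stood at 3286 ± 123 against 2260 ± 70.4 CPM. Tests gave H2-Ab1 (0.54 ± 0.051, adjusted p = 5.96e-08), H2-DMb2 (0.98 ± 0.068, adjusted p = 3.73e-10), Cd1d1 (1.43 ± 0.079, adjusted p = 5.83e-12) and the class II transactivator Ciita (0.69 ± 0.072, adjusted p = 2.83e-07). In the proliferation list, 24 of 30 rose and 1 fell (25 and 1 adjusted over the list alone, median log2 1.02, camera adjusted p = 9.65e-09). Among them were Top2a (1.13 ± 0.15, adjusted p = 7.79e-06) and Ccnb2 (1.90 ± 0.28, adjusted p = 2.51e-05). Of B cell genes, 14 of 16 rose and 0 fell (15 and 0 adjusted over the list alone, median log2 0.62, camera adjusted p = 1.19e-13). 1 of them was Spib (1.25 ± 0.091, adjusted p = 8.31e-10).

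In the heat shock and immediate early list, 1 of 32 rose and 20 fell (1 and 21 adjusted over the list alone, median log2 -0.24, camera adjusted p = 1.19e-13). Among them were Egr1 (-0.87 ± 0.052, adjusted p = 2.53e-11) and Zfp36 (-0.58 ± 0.054, adjusted p = 4.55e-08). Of NF-kB genes, 1 of 25 rose and 13 fell (2 and 13 adjusted over the list alone, median log2 -0.28, camera adjusted p = 2.10e-07). Among them were Cxcl1 (-1.23 ± 0.078, adjusted p = 6.39e-11), Tnfaip3 (-0.46 ± 0.042, adjusted p = 2.97e-08) and the prostaglandin synthase gene Ptgs2 (-0.58 ± 0.061, adjusted p = 3.89e-07). 

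Among the largest rises were the Notch ligand gene Dll4 (3.15 ± 0.13, adjusted p = 4.71e-14), Flg2 (3.30 ± 0.36, adjusted p = 4.99e-07), Fat3 (3.08 ± 0.40, adjusted p = 5.04e-06), Gprin2 (3.02 ± 0.35, adjusted p = 1.08e-06), Eppk1 (2.92 ± 0.30, adjusted p = 2.02e-07), Zfp777 (2.55 ± 0.24, adjusted p = 6.04e-08), Dnm3 (2.47 ± 0.37, adjusted p = 3.67e-05) and the repeated gene Duxf3 (3.35 ± 0.30, adjusted p = 2.40e-08), whose level is uncertain. Falls of protein-coding genes were led by Mucl1 (-1.99 ± 0.33, adjusted p = 0.000104), Cd209e (-1.27 ± 0.27, adjusted p = 0.00117) and Zfp938 (-1.25 ± 0.34, adjusted p = 0.00867), and Pde2a (-2.37 ± 0.77, adjusted p = 0.024) lost its call without replicate 1 or 2 of mDC TDLN CIS (adjusted p = 0.0738 and 0.113) and with DESeq2 (adjusted p = 0.462). The pseudogenes Gnb1-ps3, Tcea1-ps1, Rps6-ps4 and Znf41-ps were also among the largest falls (-1.41, -1.38, -1.35 and -1.33), with reads that parent genes may share. Of 36 lists 17 were called, 8 with an estimated correlation.

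Cisplatin against PBS in mDC of the LN (3 against 3) raised MHC class II, stress response, cDC2 and B cell genes and lowered cholesterol synthesis genes. Of 12519 genes 770 rose and 604 fell. In the MHC class II list, 11 of 14 rose and 0 fell (the same adjusted over the list alone, median log2 0.60, camera adjusted p = 2.07e-24). Among them were H2-Ab1 (0.83 ± 0.051, adjusted p = 7.16e-11) and H2-Aa (0.42 ± 0.042, adjusted p = 1.88e-07). Of cholesterol synthesis genes, 0 of 22 rose and 14 fell (0 and 16 adjusted over the list alone, median log2 -0.49, camera adjusted p = 1.17e-18). Among them were Hmgcs1 (-0.82 ± 0.073, adjusted p = 3.23e-08) and Insig1 (-0.95 ± 0.099, adjusted p = 2.90e-07). In the heat shock and immediate early list, 20 of 32 rose and 5 fell (22 and 5 adjusted over the list alone, median log2 0.35, camera adjusted p = 1.27e-11). Among them were Nr4a1 (0.69 ± 0.055, adjusted p = 5.79e-09) and Egr2 (1.37 ± 0.12, adjusted p = 1.79e-08), while Egr1 (-0.50 ± 0.054, adjusted p = 5.47e-07) fell.

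Of cDC2 genes, 5 of 10 rose and 1 fell (6 and 1 adjusted over the list alone, median log2 0.58, camera adjusted p = 1.19e-09). The monocyte and lymph node macrophage lists moved with them (median log2 0.48 and 0.21, camera adjusted p = 0.000131 and 5.21e-05). Among the cDC2 genes were Cd209a (2.30 ± 0.13, adjusted p = 3.04e-11) and Mgl2 (2.65 ± 0.16, adjusted p = 3.04e-11), while Irf4 (-0.66 ± 0.10, adjusted p = 6.05e-05) fell. In the B cell list, 14 of 16 rose and 0 fell (the same adjusted over the list alone, median log2 0.99, camera adjusted p = 1.62e-26). Its members include Cd79a (1.22 ± 0.12, adjusted p = 8.66e-08). Largest rises were Ngp (3.92 ± 0.62, adjusted p = 0.000111), Ranbp9 (3.43 ± 0.23, adjusted p = 3.95e-10), Sycn (3.34 ± 0.37, adjusted p = 7.40e-07), Clps (3.11 ± 0.21, adjusted p = 4.51e-10) and Reg1 (2.94 ± 0.33, adjusted p = 1.10e-06). Largest falls were Nuak1 (-2.07 ± 0.38, adjusted p = 0.000668), the lymphoid chemokine gene Ccl21a (-2.06 ± 0.38, adjusted p = 0.000561), Cd209b (-1.63 ± 0.32, adjusted p = 0.00126) and Sema7a (-1.55 ± 0.22, adjusted p = 2.21e-05), and Ly6i (-1.96 ± 0.53, adjusted p = 0.016) lost its call without replicate 1 or 3 of mDC LN CIS (adjusted p = 0.0964 and 0.0684). Of 36 lists 18 were called, 11 with an estimated correlation.

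In mDC with PBS, TDLN against LN (3 against 3) showed lower MHC class II and NF-kB genes and higher B cell genes. Of 12519 genes 1849 were higher and 1790 lower. With the deep TDLN libraries thinned 2836 genes passed, and 11594 with no low-count filter. Of MHC class II genes, 0 of 14 were higher and 11 were lower (1 and 11 adjusted over the list alone, median log2 -0.41, camera adjusted p = 2.08e-10). Among them were H2-Aa (-0.61 ± 0.042, adjusted p = 3.57e-10) and H2-Eb1 (-0.77 ± 0.054, adjusted p = 3.79e-10). In the NF-kB list, 1 of 25 was higher and 12 were lower (2 and 14 adjusted over the list alone, median log2 -0.27, camera adjusted p = 0.000244, adjusted p = 0.169 with an estimated correlation). Among them were Nfkbiz (-0.50 ± 0.046, adjusted p = 3.32e-08) and Il12b (-0.52 ± 0.062, adjusted p = 1.46e-06).

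Of B cell genes, 13 of 16 were higher and 1 was lower (the same adjusted over the list alone, median log2 0.74, camera adjusted p = 2.44e-06). 1 of them was Fcer2a (1.01 ± 0.14, adjusted p = 9.10e-06). The genes most increased in the TDLN were the ubiquitin ligase genes Znrf2 (2.48 ± 0.14, adjusted p = 4.66e-12) and Cul3 (2.44 ± 0.16, adjusted p = 1.18e-10), and Tada2b (2.11 ± 0.21, adjusted p = 1.83e-07), Heca (2.10 ± 0.14, adjusted p = 3.46e-10) and Insm1 (2.04 ± 0.094, adjusted p = 1.68e-13). Lower by most were Flg2 (-3.81 ± 0.35, adjusted p = 3.85e-08), Fat2 (-3.52 ± 0.41, adjusted p = 1.11e-06), the lincRNA AC166110.4 (-3.60 ± 0.49, adjusted p = 9.20e-06) and the uncertain Duxf3 (-3.53 ± 0.31, adjusted p = 1.38e-08). Of 36 lists 10 were called, 3 with an estimated correlation.

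The cisplatin effect in mDC differed between nodes for 1952 of 12519 genes (1055 higher and 897 lower in the TDLN), and for 5357 with no low-count filter. Immediate early and heat shock genes, which rose in the LN and fell in the TDLN, led this: 0 of 32 were higher and 25 were lower (0 and 28 adjusted over the list alone, median log2 -0.58, camera adjusted p = 6.60e-31). Members included Nr4a1 (-0.79 ± 0.077, adjusted p = 1.75e-07), Egr2 (-1.61 ± 0.16, adjusted p = 2.45e-07) and Fos (-0.65 ± 0.066, adjusted p = 2.51e-07). In the cholesterol synthesis list, 14 of 22 were higher and 0 were lower (the same adjusted over the list alone, median log2 0.54, camera adjusted p = 4.81e-09). Among them were Fdps (1.06 ± 0.12, adjusted p = 2.61e-06) and Hmgcs1 (0.68 ± 0.097, adjusted p = 3.34e-05). The lectin genes Cd209a (-3.25 ± 0.22, adjusted p = 3.83e-10), Mgl2 (-2.84 ± 0.24, adjusted p = 1.36e-08) and Cd209e (-2.72 ± 0.37, adjusted p = 2.08e-05) had the lowest effects in the TDLN relative to the LN.

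In rDC of the TDLN (3 against 3) cisplatin raised interferon and complement genes and lowered T cell and migratory dendritic cell genes. Of 14023 genes 56 rose and 86 fell, all 142 without overlap between the groups, and 12.6% of tested genes did not overlap (10% by chance). The count became 613 without rDC TDLN CIS 2, and 87, 82 and 88 without PBS 1, 2 and 3. With DESeq2 it was 216, with no low-count filter 235, and 88 with the 6 libraries alone.

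Of type I interferon genes, 4 of 32 rose and 0 fell (21 and 0 adjusted over the list alone, median log2 0.43, camera adjusted p = 1.24e-22). Its members include Oas2 (1.15 ± 0.19, adjusted p = 0.00405). In the complement list, 3 of 14 rose and 0 fell (8 and 0 adjusted over the list alone, median log2 0.47, camera adjusted p = 2.64e-09). The lymph node macrophage and monocyte lists moved with it (median log2 0.44 and 0.22, camera adjusted p = 2.64e-09 and 0.000524). 1 of them was C3 (0.91 ± 0.14, adjusted p = 0.00164). The heat shock genes Hspa1a (1.26 ± 0.17, adjusted p = 0.000479) and Hspa1b (1.18 ± 0.14, adjusted p = 0.000113), near-identical copies, and Tmem26 (1.89 ± 0.25, adjusted p = 0.000439) rose. The chitinase-like gene Chil3 (2.06 ± 0.38, adjusted p = 0.0085) lost its call without replicate 2 of rDC TDLN PBS (adjusted p = 0.0538). Rises of Clec5a (1.36 ± 0.31, adjusted p = 0.0429), Hap1 (1.21 ± 0.22, adjusted p = 0.00646) and Cfb (1.14 ± 0.21, adjusted p = 0.00826) were lost without replicate 1 or 3 of rDC TDLN CIS (adjusted p = 0.116 and 0.105) or replicate 1, 2 or 3 of rDC TDLN PBS (adjusted p = 0.268, 0.0964 and 0.101) for Clec5a, replicate 1 or 3 of rDC TDLN PBS (adjusted p = 0.0602 and 0.0503) for Hap1 and replicate 1 or 3 of rDC TDLN PBS (adjusted p = 0.0579 and 0.0574) for Cfb.

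In the T cell list, 0 of 18 rose and 12 fell (0 and 15 adjusted over the list alone, median log2 -1.24, camera adjusted p = 3.82e-65). Among them were Tcf7 (-1.39 ± 0.13, adjusted p = 1.08e-05) and Cd3d (-2.31 ± 0.25, adjusted p = 4.07e-05). Of migratory dendritic cell genes, 0 of 15 rose and 5 fell (0 and 9 adjusted over the list alone, median log2 -0.43, camera adjusted p = 7.38e-17). Among them were Ccl22 (-1.51 ± 0.19, adjusted p = 0.000289) and Fscn1 (-1.13 ± 0.15, adjusted p = 0.000352). The elastase gene Cela2a stood at 4.36 ± 2.05 against 64.7 ± 4.78 CPM and gave Cela2a (-3.86 ± 0.23, adjusted p = 4.40e-08), and Ctrb1 (-4.17 ± 0.56, adjusted p = 0.00045), Clps (-4.16 ± 0.43, adjusted p = 3.07e-05), Rnase1 (-3.58 ± 0.32, adjusted p = 5.40e-06) and Cpb1 (-3.41 ± 0.49, adjusted p = 0.000748) fell too. For Amy2a1 (-4.07 ± 0.60, adjusted p = 0.00111), Try4 (-3.52 ± 0.29, adjusted p = 2.59e-06) and Prss2 (-3.44 ± 0.24, adjusted p = 1.93e-07), members of families of near-identical genes, the assignment is uncertain. Whether rDC or other tissue in the digested nodes carried the RNA of Cela2a and these further genes was not tested. Of 36 lists 15 were called, 11 with an estimated correlation.

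Cisplatin against PBS in rDC of the LN (3 against 3) raised T cell and NK cell genes, while dendritic cell maturation, resident cDC1 and MHC class II genes fell. Of 14023 genes 1504 rose and 1005 fell. The 2509 genes became 1622 with the deeper PBS libraries thinned, 4707 with the 6 libraries alone, 7427 with no low-count filter and 1581 without rDC LN CIS 2. In the T cell list, 16 of 18 rose and 0 fell (17 and 0 adjusted over the list alone, median log2 2.31, camera adjusted p = 1.27e-60). Among them were Tcf7 (2.21 ± 0.12, adjusted p = 1.32e-08), Ms4a4b (2.52 ± 0.16, adjusted p = 2.99e-08) and the CD3 chain gene Cd3e (2.83 ± 0.19, adjusted p = 8.69e-08). Of NK and innate lymphoid genes, 12 of 13 rose and 0 fell (the same adjusted over the list alone, median log2 2.88, camera adjusted p = 2.17e-43). The receptor gene Klrb1c stood at 19.5 ± 3.27 against 0.566 ± 0.165 CPM, and Klrb1c (5.02 ± 0.29, adjusted p = 1.40e-08), Gzma (4.20 ± 0.40, adjusted p = 2.89e-06), Ncr1 (3.92 ± 0.36, adjusted p = 2.39e-06), Il2rb (3.10 ± 0.18, adjusted p = 2.05e-08) and Nkg7 (3.30 ± 0.25, adjusted p = 2.32e-07) rose, as did Klrc1 (3.56 ± 0.37, adjusted p = 7.13e-06) and the death ligand gene Fasl (3.53 ± 0.39, adjusted p = 1.37e-05).

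Of dendritic cell maturation genes, 2 of 27 rose and 12 fell (the same adjusted over the list alone, median log2 -0.32, camera adjusted p = 2.59e-07). Among them were the interleukin-12 subunit gene Il12b (-1.90 ± 0.15, adjusted p = 5.40e-07), Fscn1 (-1.78 ± 0.15, adjusted p = 8.42e-07) and Cd83 (-0.69 ± 0.066, adjusted p = 2.82e-06), while Ccl5 (1.59 ± 0.16, adjusted p = 7.13e-06) rose. In the resident cDC1 list, 1 of 11 rose and 9 fell (1 and 10 adjusted over the list alone, median log2 -0.59, camera adjusted p = 3.25e-09). Among them were Naaa (-0.73 ± 0.071, adjusted p = 3.66e-06) and Xcr1 (-0.74 ± 0.092, adjusted p = 4.50e-05), while Itgae (0.84 ± 0.13, adjusted p = 0.000468) rose. In the MHC class II list, 0 of 14 rose and 8 fell (0 and 11 adjusted over the list alone, median log2 -0.32, camera adjusted p = 2.39e-05, adjusted p = 0.179 with an estimated correlation). Among them were H2-Aa (-0.54 ± 0.079, adjusted p = 0.000229) and H2-Eb1 (-0.59 ± 0.093, adjusted p = 0.000451). Falls of Rsc1a1 (-2.57 ± 0.77, adjusted p = 0.0273) and the pseudogene Rpl19-ps11 (-1.83 ± 0.49, adjusted p = 0.0158) were lost without replicate 1 or 3 of rDC LN CIS (adjusted p = 0.0747 and 0.113) or replicate 1 or 2 of rDC LN PBS (adjusted p = 0.0647 and 0.0593) for Rsc1a1 and replicate 2 of rDC LN CIS (adjusted p = 0.0562) for Rpl19-ps11, and the pseudogene Rps23-ps1 (-1.83 ± 0.43, adjusted p = 0.00715) may share reads with its parent gene. Of 36 lists 18 were called, 8 with an estimated correlation.

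**Figure D4:**
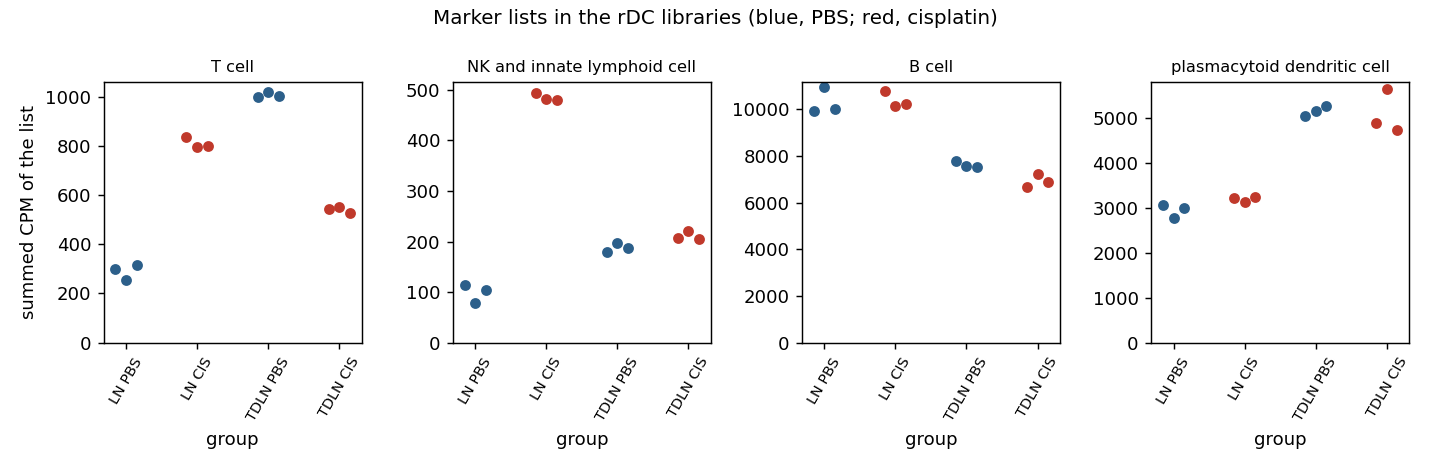
Summed CPM of 4 marker lists (panels) in the 12 rDC libraries by group (x axis), 1 point per library, blue for PBS and red for cisplatin. T cell genes sum to 253.9 to 315.1 CPM in LN PBS and 998.8 to 1020.2 in TDLN PBS.

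In rDC with PBS, TDLN against LN (3 against 3) showed higher T cell and plasmacytoid genes and lower B cell and interferon genes. Of 14023 genes 2089 were higher and 1692 lower. The 3781 became 2897 with the deep LN libraries thinned, 2366 without rDC LN PBS 2, 5829 with the 6 libraries alone and 6354 with no low-count filter. In the T cell list, 17 of 18 were higher and 0 were lower (the same adjusted over the list alone, median log2 2.38, camera adjusted p = 1.62e-59). Among them were Tcf7 (2.33 ± 0.12, adjusted p = 2.31e-09) and Cd3e (3.06 ± 0.19, adjusted p = 1.53e-08). Of plasmacytoid genes, 10 of 10 were higher and 0 were lower (the same adjusted over the list alone, median log2 0.92, camera adjusted p = 6.94e-18). Among them were Siglech (0.95 ± 0.068, adjusted p = 7.07e-08) and Ccr9 (0.90 ± 0.066, adjusted p = 9.11e-08). In the B cell list, 1 of 16 was higher and 13 were lower (2 and 13 adjusted over the list alone, median log2 -0.65, camera adjusted p = 2.17e-11). Its members include Fcer2a (-0.81 ± 0.079, adjusted p = 1.83e-06).

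Of type I interferon genes, 1 of 32 was higher and 13 were lower (1 and 15 adjusted over the list alone, median log2 -0.37, camera adjusted p = 0.000229). Among them were Ifit3 (-0.95 ± 0.15, adjusted p = 0.000264) and Rtp4 (-1.02 ± 0.19, adjusted p = 0.00101). Genes named for the largest increase were Cela3b (3.95 ± 0.36, adjusted p = 1.18e-06), Rnase1 (3.83 ± 0.26, adjusted p = 3.04e-08) and, uncertain because of near-identical copies, Try4 (4.13 ± 0.25, adjusted p = 8.24e-09), Amy2a2 (3.79 ± 0.35, adjusted p = 1.24e-06) and Amy2a3 (3.79 ± 0.35, adjusted p = 1.24e-06). The resistin-like gene Retnla (-3.30 ± 0.46, adjusted p = 6.31e-05), Lrrcc1 (-1.69 ± 0.25, adjusted p = 0.000151), AC163635.1 (-1.51 ± 0.19, adjusted p = 2.80e-05) and the pseudogene Nlrp1c-ps (-1.55 ± 0.29, adjusted p = 0.000954) were lower, and the pseudogene Rps25-ps1 (-2.53 ± 0.65, adjusted p = 0.00932) lost its call without replicate 1 of rDC TDLN PBS (adjusted p = 0.0546). Of 36 lists 14 were called, 5 with an estimated correlation.

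T cell genes in rDC, which rose with cisplatin in the LN and fell in the TDLN, gave the clearest difference between nodes. It was tested for 14023 genes, of which 367 had a higher and 378 a lower effect in the TDLN. The 745 became 1784 without rDC TDLN CIS 2, 485 without rDC TDLN PBS 3 and 1845 with no low-count filter. In the T cell list, 0 of 18 were higher and 16 were lower (0 and 18 adjusted over the list alone, median log2 -3.52, camera adjusted p = 8.34e-122). Among them were Tcf7 (-3.60 ± 0.18, adjusted p = 2.95e-09) and Cd3e (-4.65 ± 0.28, adjusted p = 2.16e-08). Of NK and innate lymphoid genes, 0 of 13 were higher and 9 were lower (0 and 11 adjusted over the list alone, median log2 -2.70, camera adjusted p = 3.27e-19). Among them were Il2rb (-2.96 ± 0.26, adjusted p = 1.72e-06), Nkg7 (-3.55 ± 0.38, adjusted p = 1.34e-05) and the perforin gene Prf1 (-2.70 ± 0.33, adjusted p = 5.81e-05). Clps (-6.24 ± 0.55, adjusted p = 1.73e-06) and Cela2a (-5.66 ± 0.31, adjusted p = 9.39e-09) were among the genes with the lowest effects in the TDLN relative to the LN.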

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

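Tests of the first 3 patterns were chosen after the results were seen, and counts over regrouped libraries by a rule set beforehand.

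Of the 24 macrophage libraries, 4 carried the expression pattern of the other label. An exchange of labels within LN PBS and within TDLN cisplatin could produce this. Each of the 4 correlated at 0.989 or more with libraries of the other label, against 0.747 or less with its own. A minority of cells of the other type mixed in would place genes between both labels. Over genes more than 4-fold apart the libraries lay at a median position of 0.987 to 1 on a scale from the own label (0) to the other (1), which leaves little room for a mixture.

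Lymph node macrophage genes fell with cisplatin in MSM of the LN. Cells other than macrophages in the sort may account for this, since 9 of 16 migratory dendritic cell genes had their highest level of all macrophage groups here, against 22.6% of genes (exact binomial p = 0.00359). Too few counts in these libraries is unlikely, because the macrophage list had a median lowest level of 41.4 CPM in other groups, where 3 counts give at most 0.43 CPM. Cisplatin acting on MSM of the LN may also be the cause, which 1 such group cannot tell apart.

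T cell genes differed between rDC groups in both directions. The median log2 for TDLN against LN was 2.40 after thinning and 2.38 before. Random thinning keeps the expected share of each gene, so this median could hardly move and does not test depth. The deep rDC libraries made up LN PBS, so whatever went with their depth cannot be told apart from the group. T cells or their RNA in the sorted sample and regulation within rDC cannot be told apart, because either could give the negative log2 fold change of 18 of 18 members with cisplatin in the TDLN (12 passed 0.05), and no sorted T cells were measured. A lower share of rDC raising the genes of every other cell type stays open too. With cisplatin in the LN the B cell list had a median of 0.01 where the T cell list had 2.31, but its sum of 9913.0 to 10941.6 CPM in LN PBS would hide a small share, and the NK list had 2.88.

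Libraries were regrouped to see whether any grouping would call as many genes. In each comparison of 3 against 3 the real grouping called most genes of 10 splits (highest other 3). That is too few splits for a share under 0.05. For node differences with 60 splits the real count was reached by 1 split, the real one, in MSM (6928, highest other 1935), SSM (3649, 574) and mDC (1952, 912). In rDC the real 745 was reached by 2 of 60 splits, and the other called 1601 genes. With 40 splits MSM against SSM gave 5942 and at most 5188, and mDC against rDC 10829 and at most 385.

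The effect of cisplatin differed between TDLN and LN for 7 lists in MSM, 14 in SSM, 14 in mDC and 19 in rDC. With an estimated correlation 0, 0, 6 and 4 of these held. Fitted differences resting on groups at 0 counts give direction only. In MSM the extremes were Wasf1 (22.34), Trpv4 (20.39), Gstm4 (19.93), Stag3 (-12.87), Enho (-12.47) and Gzma (-11.96), and Il1rl1 had 6.96. In SSM they were Tpsb2 (25.49), Mcpt4 (25.39), Tpsab1 (22.49), Sparcl1 (-13.25), Igfbp6 (-10.94) and Olfr523 (-10.77). In mDC they were Zfp433 (5.26), Flg2 (3.61), Fat3 (3.61), Cd209a (-3.25), Mgl2 (-2.84) and Cd209e (-2.72). In rDC they were Clec5a (2.33), ENSMUSG00000118491 (2.31), Bcl2a1a (2.11), Clps (-6.24), Amy2a1 (-5.97) and Cela2a (-5.66).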

How the results depend on the processing

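Counts of called genes depended most on the crossed macrophage libraries, and the cause was not tested. Without them MSM called 12674 genes (cisplatin in TDLN), 13602 (cisplatin in LN), 12812 (TDLN against LN) and 11954 (node difference), and SSM 12540, 10574, 11947 and 11607 in the same order. MSM against SSM called 11624, and 11675 when the MSM LN cisplatin group was left out too. Of 265 called macrophage gene values 222 kept the call in every alternative, 38 lost it in some and 5 reversed. Of 302 in dendritic cells 274 kept it and 28 lost it.

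With a replicate block SSM called 2476, 1206, 2118 and 2375 genes in that order. The camera test lost with it the B cell, plasma cell and monocyte lists for cisplatin in MSM of the TDLN (adjusted p = 0.0656, 0.0567 and 0.0656). It also lost the efferocytosis, lymph node macrophage and neutrophil lists of the MSM node difference (0.0889, 0.0696 and 0.0818), and in SSM the cDC2 list for TDLN against LN (0.0654) and the plasmacytoid list of the node difference (0.0618). With 3 libraries per group pairing by replicate number stays open. Only mDC cisplatin in the TDLN had 3 of 3 libraries closest to their own number (r from 0.039 to 0.179). With no low-count filter the counts were 1448 for SSM cisplatin in LN, 9422, 11594 and 5357 for mDC cisplatin in TDLN, TDLN against LN and node difference, and 235, 7427, 6354 and 1845 for rDC. DESeq2 called 3554 for SSM cisplatin in LN and 216 for rDC cisplatin in TDLN. With the 6 compared libraries alone rDC called 88, 4707 and 5829, and with deep libraries thinned 1622 for cisplatin in LN.

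Leaving out 1 library gave 1818 to 8810, 803 to 4441, 1400 to 6471 and 2170 to 7440 genes in SSM. In rDC it gave 82 to 613, 1581 to 2043, 2366 to 3182 and 485 to 1784.

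Il33 and Il1rl1 changed sign in some fits. For Il33 with cisplatin in MSM of the TDLN, leaving out 1 library gave -8.60 to -0.38. In MSM of the LN this gave -9.12 to 0.00, with 0.00 also without the crossed libraries. TDLN against LN in MSM gave -0.48 to 8.61 for Il33, and -0.41 without MSM LN PBS 1. Its node difference in MSM gave -0.94 to 8.17, -0.07 without MSM TDLN CIS 1 and -8.58 without the crossed libraries. Il1rl1 in SSM gave -1.21 to 0.17 for cisplatin in LN (0.17 without the crossed libraries) and -0.96 to 0.41 for TDLN against LN (0.41, adjusted p = 0.0205, without the crossed libraries), and its node difference became -0.15 without them. Il33 in rDC gave -0.16 to 2.04 for TDLN against LN and -1.51 to 0.70 for the node difference. In MSM against SSM without the crossed and LN cisplatin libraries Il13ra1 became 0.12, Lyz2 0.30, Maf 0.45, Adgre1 1.06 and Il1rl1 1.3 (0.08 without the crossed libraries alone).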

Other observations

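Many genes were silent in single macrophage groups. Of 8459 genes with at least 10 CPM in every library of 4 or more other groups, 130 had at most 3 counts in the 3 MSM LN cisplatin libraries together, and their median elsewhere was 23.4 CPM. In MSM TDLN PBS this held for 102 of 8491 genes (median elsewhere 19.3 CPM). SSM LN cisplatin and SSM TDLN PBS had 1 such gene each and dendritic cell groups 1 to 7. The other 4 macrophage groups each hold a crossed library, so cannot be compared this way.

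Pmel averaged 577 CPM in SSM LN cisplatin and at most 40.8 CPM in any other macrophage group, scaled over all 24 libraries. In rDC Cela2a averaged 64.7 CPM in TDLN PBS and 4.36 CPM in TDLN cisplatin.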
